A study of Schizosaccharomyces pombe with 9 samples.

How the data were processed

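Chromatin from fission yeast grown in rich medium was immunoprecipitated for dimethylated histone H3 lysine 9, for Fep1-GFP or for Ssn6-Myc, and hybridised with whole-cell extract DNA on 9 two-colour Agilent tiling arrays of the same 44k design. Per the labels, cultures for 18 °C were grown at 30 °C and then kept at 18 °C for 3 days, cells were fixed with 3% paraformaldehyde, and Fep1-GFP cells were also treated with the crosslinker dimethyl adipimidate for 45 minutes. The sheared fragments were 500 to 1000 bp long and were amplified by random-primed PCR before labelling. ChIP DNA carried Cy5 and whole-cell extract DNA Cy3. The labels name the H3K9me2 and GFP antibodies but not the Myc antibody, give no temperature for the Fep1 and Ssn6 cultures, and spell Fep1 as Feb1 in places. Groups were taken from the labels, and each had 1 array.

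Per the file headers, the processed signal of each dye is an intensity that Agilent Feature Extraction 12.0.3.1 had subtracted for background, detrended and scaled by a linear dye normalization factor, with no LOWESS step. The median spot and local background signals, per the file headers, are intensity values with nothing further done to them. The scanner files also hold, as deposited, a ratio column in log10 units, Cy5 over Cy3, which equals the log10 ratio of the processed signals for nearly all probes. The Fep1-GFP file had been saved again with rounded values. The series value table, as deposited by the authors, holds log2 ratios of Cy5 over Cy3 without centring. Of its values, 33.3% for Fep1-GFP and 29.0% for Ssn6 without fep1 closely matched some log2 ratio of the scanner file, against at least 96.1% in the other columns. Its identifiers did not pair with those of the scanner files, since the correlation of values by identifier lay between −0.026 and 0.138 over the arrays. Its column medians were −0.059 for Fep1-GFP, −0.072 for the ago1 deletion, −0.031 for the ccr4 deletion, −0.072 for the double mutant, −0.037 for bipyridyl, −0.016 and −0.021 for wild type at 18 °C and 30 °C, and −0.134 and −0.12 for Ssn6 with and without fep1. Which probe each of its values belongs to stays unknown, so it was not used for any result.

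The main value was the log2 ratio of Cy5 over Cy3 processed signals, centred on the array median over the 41551 non-control probes. Probes were left out on an array where Cy3 was not well above background or where a spot was marked as non-uniform. Of the probes, 41251 lie on the 3 chromosomes, in tiles of 300 bp, and 300 lie on a mating-type contig, the mitochondrial genome and telomere-linked clones. The headers name no genome build, and the probe positions did not match the annotated genome (assembly ASM294v3) as they stood. Each chromosome was therefore divided into segments, and the shift of each segment was found by matching Cy3 signal to the GC content of 60 bp windows in steps of 20 bp, within 6000 bp and in bins of 30000 bp. This gave 7 segments with shifts from −1680 to 4480 bp and correlations from 0.297 to 0.339, against −0.028 to 0.363 without a shift. In 1 segment, II 300 to 90000 with 244 probes, the chosen shift of −80 bp had a lower correlation, 0.297, than no shift, 0.363. The matching served only to tie probes to gene names. All positions printed are those of the array design, and no build is claimed for them. Probes in repeated sequence were found as tiles of which at least 50% is made of 30-mers present more than once in the genome, which held for 1183 probes. Of the probes whose names mark them as multi-copy, 73.5% fell in such tiles, against 0.2% of the others.

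For H3K9me2, a gene's value was the mean over the probes centred in it, with at least 3 probes measured on both arrays compared, for 5113 protein-coding genes of the annotation. A gene counted as gained or lost when the arrays differed by at least 1.5-fold and the higher one was at least 2-fold above the array median. For Fep1-GFP and Ssn6-Myc, a promoter was the 1000 bp upstream of a gene, with at least 2 probes, and a promoter counted as bound by Fep1-GFP from 2-fold on. Genes called in one comparison within 10 kb of each other were counted as 1 locus. Places near chromosome ends, pericentromeres and the mating-type region were taken to 100 kb, and subtelomeres as the outer 50 kb of chromosomes I and II. Domains were runs of at least 3 probes at 2-fold or more after averaging over 500 bp on either side, joined across gaps of up to 1000 bp. With 1 array per group there were no replicates, no test between groups and no p-values. Intervals are 95% bootstrap intervals over genes, promoters or probes from 10000 resamples, and say nothing about replicate error.

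The gene lists were 14: iron uptake under Fep1, iron-using proteins, DSR meiotic genes, mating and sexual differentiation, Tf2 retrotransposons, wtf genes, phosphate genes, stress genes, hexose transport and carbon, amino acid and nitrogen transport, heterochromatin and RNA elimination machinery, housekeeping controls, ribosomal proteins, and subtelomeric genes. Each list's median was placed among 10000 random lists of the same size matched on 5 bins of Cy3 signal, and called outside when below the 2.5 or above the 97.5 percentile. Random lists take no account of neighbouring genes that share a domain, which matters most for the subtelomeric list. List medians were not rerun without repeated probes, so signal shared between copies of a repeat, as for Tf2, was not removed from them. One listed symbol, aap1, was not found in the annotation and was left out, and tim18, num1, jnm1 and dli1 were matched through older names. The genes named in the text were the 10 in each direction with the largest difference (12 for Fep1-GFP), among those called with at least 80% of their probes in that direction, and at most 1 per 10 kb. To these were added the 2 to 4 members of each list with the largest values and the targeted genes ago1, ccr4 and fep1. The groups, comparisons, size rule, lists, naming rule and most alternatives were fixed before the data were examined.

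The alternatives were normexp background correction with an offset of 50 on median signals, loess within each array, centring on the housekeeping genes, no filter on dim probes, the median over probes, a 2-fold difference (3-fold for Fep1-GFP), an enrichment floor of 1.5-fold, removal of repeated probes, rescaling to the same pericentromeric median, a 500 bp promoter window, and for domains other thresholds and no smoothing. Random lists were also matched on the log2 ratio. Keeping non-uniform spots, 1 common Cy3 level per probe from all 9 arrays, removing saturated Cy5 probes and list medians centred on housekeeping genes were added after the data had been seen.

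The median Cy3 signal was 8551.0 for wild type at 30 °C, 7610.2 for wild type at 18 °C, 10259.9 for the ago1 deletion, 9462.5 for the ccr4 deletion, 13400.1 for the double mutant, 9542.7 for bipyridyl, 10321.5 for Fep1-GFP, and 11906.0 and 13536.9 for Ssn6 with and without fep1. The median Cy5 signals, in the same order, were 1490.8, 1320.3, 1997.6, 1158.3, 1421.8, 949.7, 4873.7, 9159.2 and 16866.8. Local backgrounds had medians of 93.5 to 301.5 in Cy3 and 59.0 to 114.5 in Cy5. The spread of the log2 ratio between neighbouring probes had an SD of 0.378 on the ago1 deletion array and of 0.164 on the Fep1-GFP array, the extremes of the series. Both wild-type H3K9me2 arrays were scanned at 16 bits, with 633 and 605 saturated Cy5 spots at 18 °C and 30 °C, and the other arrays at 20 bits with 0. Non-uniform Cy5 spots numbered 4226 on the bipyridyl array, 2922 on the ccr4 deletion array and 2444 on the double mutant array, and at most 163 on each of the others. The number of arrays limits the precision of every comparison.

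The procedure was tested on simulated data. With probe noise as the only noise, the size rule found 100 of 100 genes planted with a log2 difference of 1 in each comparison. It made 0 false calls among the rest, but these were simulated at a level of 0, far below the 2-fold floor. That outcome was fixed beforehand and says nothing about false calls at enriched genes. The position matching put 98.1% of 14836 simulated probes within their tile. Of 100 lists left unmoved 4 fell outside the random range, and of 100 lists moved by 0.5 log2, 95 did. All 50 planted domains were found, with 0 false ones on a background that was also set at 0. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 for normexp and loess.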

Results

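The series holds 9 two-colour tiling arrays of fission yeast (Schizosaccharomyces pombe), in which DNA recovered by chromatin immunoprecipitation (ChIP) was hybridised against DNA of the whole-cell extract. Dimethylation of histone H3 lysine 9 (H3K9me2), the histone mark of heterochromatin, was measured on 6 arrays. These were wild type at 30 °C, wild type at 18 °C, and at 18 °C an ago1 deletion, a ccr4 deletion, a ccr4 deletion with a fep1 mutation, and wild type treated with the iron chelator bipyridyl. The remaining arrays measured Fep1-GFP, and Ssn6-Myc in cells with and without fep1. Fep1 is a repressor that acts when iron is plentiful, and Ssn6 belongs to a general corepressor complex. Each group had 1 array, so there were no replicates and no tests between groups, and an SD given with a value is over the probes of that gene, not over replicates. Median whole-cell extract signals lay between 7610.2 and 13536.9, and median ChIP signals between 949.7 on the bipyridyl array and 16866.8 on the Ssn6 array without fep1. All values are log2 ratios of ChIP over whole-cell extract relative to the array median. A gene gained or lost signal when it differed by at least 1.5-fold between arrays and reached 2-fold enrichment on the higher one. Positions are those of the array design. Both wild-type H3K9me2 arrays shared a slide and a scan, and every other array had its own, so differences from wild type cannot be told apart from differences between slides. The highest ChIP signals of the wild-type arrays were saturated, which taken alone makes their values in large heterochromatic regions lower bounds. Whole-cell extract signal was also low in these regions, which raises the ratio. On the wild-type 18 °C array its median was −1.01 at subtelomeres and −1.18 at pericentromeres, against 0.40 and 0.64 on the Fep1-GFP array. Bounds given below for wild-type values, and for differences from them, refer to saturation alone.

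The comparison of wild type at 18 °C with wild type at 30 °C asked how growth in the cold changed H3K9me2. Single genes scattered over the arms gained the mark, while genes beside the centromeres lost it. The largest gain was at SPAPB1A11.02, annotated as an esterase or lipase (I 2981400 to 2982300), which went from −0.02 at 30 °C to 2.92 at 18 °C, a difference of 2.94 (SD 0.05). SPBC428.10 (II 461700 to 464700) rose by 2.87 (SD 0.39) and SPBC1289.14, an adducin (II 4413900 to 4415100), by 2.79 (SD 0.28). The largest loss was at the meiotic gene mcp7 (I 579300 to 580500), which went from 4.53 to 2.35. In all, 39 of 4610 genes gained H3K9me2, at 33 separate loci, and 179 lost it, at 20 loci. Of the genes that gained, 29 lay in the chromosome arms, 5 near the ends of chromosomes I and II and 5 near the ends of III. Of those that lost, 124 lay within 100 kb of a pericentromere and 22 near the mating-type region.

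Among the further genes with the largest gains, SPBC1105.13c rose by 2.59 and SPAC977.17, a channel protein of the MIP superfamily (I 67200 to 70500), rose by 2.30 to a level of 4.50. SPCC569.03 rose by 2.07, the glycerol dehydrogenase gene gld1 by 1.92, and iec1, which encodes a subunit of the Ino80 complex, by 1.78. The glm1 and efm6 genes rose by 1.70 and 1.6. Among the losses, vps29, a retromer subunit (I 3728100 to 3729000), differed by −2.0 (SD 0.07), and pmp20 by −1.70. The pericentromere-proximal genes pdx1, hmo1, SPBC21B10.08c and cbs2 differed by −1.54, −1.5, −1.47 and −1.44. The remaining named losses were tip41 and naa40, each at −1.37, and nro1 at −1.36. Every one of these 20 genes met the rule under each alternative setting that was run.

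Meiotic genes whose transcripts carry a determinant of selective removal (DSR) included 4 losses among 17 measured, with mcp7 at −2.18, num1 at −0.99, mei4 at −0.81 and jnm1 at −0.59. The list's median difference was 0.01. Transporters of amino acids and nitrogen included 4 losses among 9, among them isp5 at −1.19, put4 at −1.09 and cat1 at −0.92. Of the stress genes, tps1 (trehalose synthesis) gained 1.01, and the list median of 0.23 over 11 genes lay outside the middle 95% of random lists. Ribosomal protein genes had a median of 0.21, also outside that range, with 0 gains and 3 losses among 57. The hexose transport list had 1 gain, gld1, and 1 loss, ght3 at −0.69. In the iron-uptake list, median 0.03 over 13 genes, the only loss was shu1, within 100 kb of an end of chromosome I, at −0.67. In the iron-using list, median 0.09 over 19 genes, it was sdh1, a succinate dehydrogenase subunit, at −1.35. The mating list held 1 gain, isp3 at 0.80. Tf2 retrotransposons had a median of −0.31, wtf genes −0.21 and phosphate genes −0.43, all outside the random range, with 0 members passing the rule; with 1 common whole-cell extract reference the wtf median turned to 0.27 and the phosphate median to 0.08. The subtelomeric, heterochromatin machinery and housekeeping lists had medians of 0.01, −0.01 and −0.09.

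**Figure D1:**
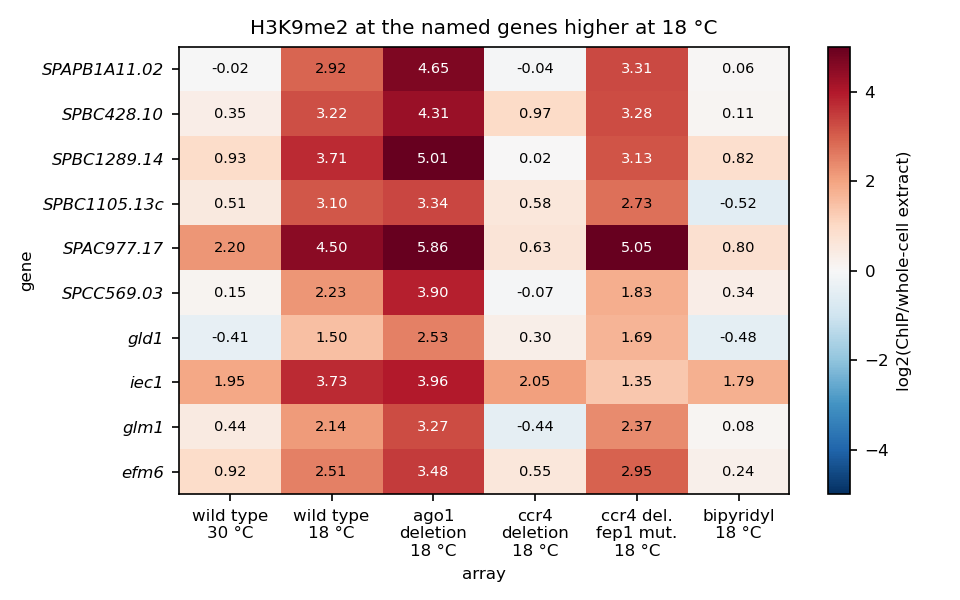
Heat map of H3K9me2 (log2 ChIP over whole-cell extract, colour and printed value) at the 10 genes with the largest gain in wild type at 18 °C over 30 °C; columns are the 6 H3K9me2 arrays, 1 per group. SPAPB1A11.02 read −0.02 at 30 °C, 2.92 at 18 °C, −0.04 in the ccr4 deletion, 3.31 with the fep1 mutation added and 0.06 with bipyridyl.

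The ago1 deletion at 18 °C was compared with wild type at 18 °C to ask what depends on Argonaute, the small-RNA-binding protein of RNA interference. The ago1 gene itself (III 333900 to 336600) had a whole-cell extract level of −6.15 in the deletion array, against 0.20 in wild type. Genes near chromosome ends and in the arms gained H3K9me2 and genes beside the centromeres lost it. The galactokinase gene gal1 (II 4490100 to 4491900) rose by 3.05 (SD 0.34) to 5.44, and SPAPJ695.02 (I 75300 to 76500) by 2.92 (SD 0.04). The uracil biosynthesis gene ura4 (III 115500 to 116400) went from at least 6.81 to 0.83, and emc5 (I 3786600 to 3787200) from 4.84 to 1.12. The whole-cell extract level of ura4 differed too, at −1.22 in wild type and 0.45 in the deletion. The nearby gene pmp20 (III 118200 to 118800) read −0.47 and −0.37. Where ura4 stands in each strain is not given in the sources used here. Of 4613 genes, 161 gained H3K9me2, at 64 loci, and 62 lost it, at 14 loci. Of the gains, 73 lay in the arms and 64 within 100 kb of the ends of chromosomes I and II, and of the losses, 52 lay near a pericentromere.

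The pfl6 gene rose by 2.61, the amino acid permease gene nrg1 by 2.47, and SPCC569.01c, SPAC977.15 and SPBPB10D8.05c by 2.32, 2.28 and 2.24. SPAC750.06c, SPBPB2B2.18 and ftm5 rose by at most 2.66, 2.42 and 2.22, since 3 probes of each were saturated in wild type. On the side of losses, the amino acid permease gene per1 differed by −2.79, ppc1 by −2.30 and the phosphomannomutase gene pmm1 by −2.01. The vps29, gpi17 and gyp2 genes differed by −1.74, −1.72 and −1.61, and tum1 by −1.52. The difference of −1.36 at SPAC8C9.04 was a minimum loss, since 3 of its probes were saturated in wild type. Subtelomeric probes had a median of 7.60 in the ago1 deletion and 6.31, a lower bound, in wild type at 18 °C, and pericentromeric probes 4.22 and 5.39. The ends of chromosome III stood at 2.07 against 0.67, and the mating-type region at 3.15 against 2.01. These 4 region differences kept their direction under every scaling that was run.

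Of the 33 subtelomeric genes measured, 27 gained and 0 lost, with a median difference of 1.48. Hexose transport genes included 3 gains among 12, namely ght3 and ght7 at 1.62 and gld1 at 1.03, and their median of 0.33 turned to −0.05 after loess. The wtf median of 0.27, with 0 genes passing the rule, likewise turned to −0.05. Mating genes had a median of 0.21 and 2 gains, isp3 at 1.09 and map1 at 0.77. These 4 medians lay outside the random range, and those of the other lists inside it. In the iron-uptake list, median 0.12, shu1 rose by 1.70 to 2.34 and str3 by 0.98. The shu1 gene lies within 100 kb of an end of chromosome I, a zone in which many genes gained. The phosphate genes pho84 and pho1 gained 1.20 and 1.10, with a list median of 0.19. The amino acid list, median 0.20, had isp5 up by 0.69 and per1, which lies near a pericentromere, down. The stress list, median 0.03, had 1 gain, tps1 at 0.62. The iron-using list lost sdh1 at −1.23, and the DSR list had num1 at 0.86 and mug9 at −0.62; the medians of both lists were 0.00. The Tf2, machinery, housekeeping and ribosomal medians were 0.12, 0.00, −0.09 and −0.11. Without saturated probes ura4, SPAC750.06c, SPBPB2B2.18 and ftm5 had too few probes left to be measured, as had 6 of the 10 named gains without probes in repeated sequence.

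**Figure D2:**
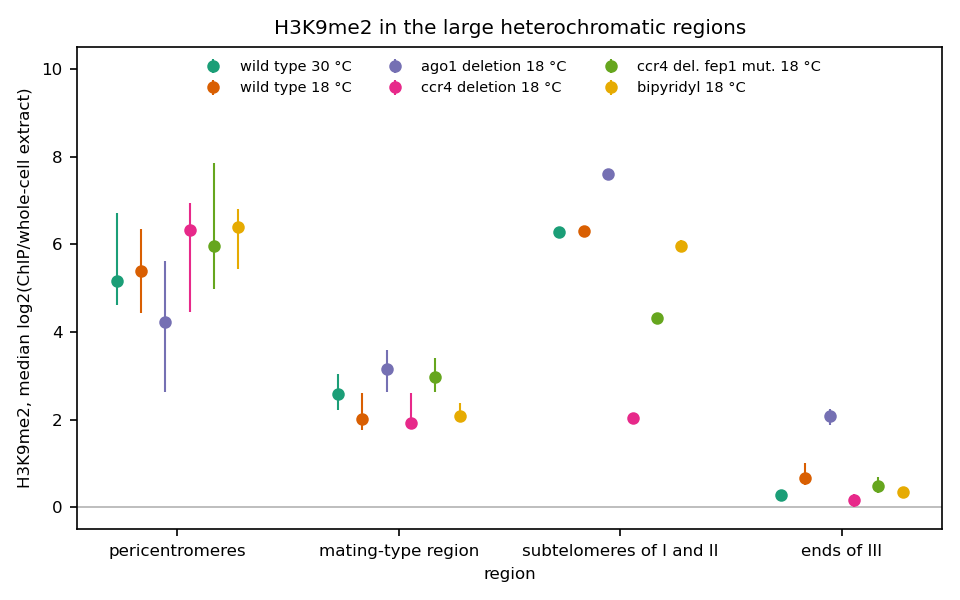
Median H3K9me2 (vertical axis, log2 ChIP over whole-cell extract) of the probes in 4 regions (horizontal axis) on the 6 H3K9me2 arrays (colours); bars are 95% bootstrap intervals over probes, not replicate error. Subtelomeres of chromosomes I and II stood at 6.31 in wild type at 18 °C, 7.60 in the ago1 deletion, 2.03 in the ccr4 deletion and 4.33 with the fep1 mutation added, where loess reduced the last difference from 2.29 to 0.37.

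The ccr4 deletion at 18 °C was compared with wild type at 18 °C. Ccr4 is a catalytic subunit of the Ccr4-Not mRNA deadenylase complex. The ccr4 gene (III 637500 to 639300) had a whole-cell extract level of −6.89 in the deletion array against 0.52 in wild type. H3K9me2 fell at most subtelomeric genes and at genes in the arms. It stayed high at the outermost genes of chromosome I, tlh1 (7.46) and SPAC750.08c (7.28), and at probes of telomere-linked clones (median 7.0). Without repeated probes tlh1 and SPAC750.08c had too few probes left to be measured, so their signal may come from other copies of the sequence. The pyruvate decarboxylase gene pdc102 (I 5548500 to 5550000) went from at least 7.59 to 1.92, a difference of −5.67, and gdt1 (I 5535600 to 5536800) from at least 6.96 to 1.52, with saturated probes in wild type at both. Of 4509 genes, 109 lost H3K9me2, at 54 loci, and 16 gained it, at 9 loci. Of the losses, 54 lay near the ends of chromosomes I and II and 47 in the arms. Of the gains, 10 lay near the mating-type region.

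Further losses near chromosome ends were SPAC977.14c at −4.88, SPAC212.04c at −4.33, SPBPB2B2.16c at −4.14 and the transporter gene SPBC1348.05 at −4.0. They continued with pfl9 at −3.90, the asparaginase gene SPBPB21E7.09 at −3.79 (SD 2.53) and SPAC977.04 at −3.54. The adducin gene SPBC1289.14, which had gained the mark in the cold, fell from 3.74 to 0.02. Without saturated probes 8 of the 10 named losses had too few probes left to be measured, and without repeated probes 6 had. Saturation in wild type understates these 8 losses, while low whole-cell extract signal in wild type would overstate them. Over the subtelomeric probes a common whole-cell extract reference reduced the median difference from −4.27 to −2.80. The sizes and order of these losses are thus not exact, and the printed sizes are not minimum losses. The named gains were smaller. The rga7 gene rose by 0.94. SPAC750.08c, rpb7 and the malate transporter gene mae1 rose by at most 1.09, 0.92 and 0.86, since 3, 1 and 2 of their probes were saturated in wild type. The RecQ helicase gene tlh1 (I 900 to 6300) read 7.46, or at most 0.85 above wild type, where 18 of its 19 probes were saturated. The pwp1 gene rose by 0.81, edc3 by 0.68 and the tropomyosin gene cdc8 by 0.61. The malic enzyme gene mae2 rose by at most 0.78, with 4 probes saturated in wild type. Subtelomeric probes had a median of 2.03 against 6.31, with the same direction under every scaling that was run, and pericentromeric probes 6.32 against 5.39, where the wild-type value is a lower bound.

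Subtelomeric genes lost in 25 cases and gained in 2 among 33, with a median of −3.59. Tf2 elements had 4 losses among 9 and a median of −0.96, led by Tf2-9 at −1.11 and Tf2-1 at −1.10. DSR genes had 5 losses among 16 and a median of −0.33, including ssm4 at −1.92, mei4 at −1.86 and mug45 at −1.07. Of the amino acid transporters, put4 fell by 1.20 and per1 by 0.76, with a list median of −0.41. The wtf median was −0.11 with 0 losses. These medians, and that of 0.58 for the housekeeping genes, lay outside the random range; of the housekeeping genes 0 passed the rule, with pgk1 at 0.99 and fba1 at 0.81. The stress list, median 0.08, had 2 losses, the glutathione peroxidase gene gpx1, from 2.57 to 1.42, and tps1 at −0.61. The hexose list, median 0.06, lost gld1 at −1.20, and the mating list, median −0.03, lost isp3 at −1.25. The remaining medians were −0.09 for iron uptake, 0.01 for iron-using proteins, 0.01 for phosphate genes, −0.12 for heterochromatin machinery and −0.05 for ribosomal proteins. Of all calls 12.8% were gains, against 0.641% when centred on housekeeping genes, 4.63% after loess and 27.0% with a common whole-cell extract reference. Housekeeping centring moved the median of all genes by −0.46, and left 1 of the 9 named gains, SPAC750.08c, all of whose 3 probes were saturated in wild type; loess left 2 and rescaling to the same pericentromeric median 3, in neither case SPAC750.08c. Without saturated probes mae1 and mae2 were measured and not called, and SPAC750.08c, rpb7 and tlh1 had too few probes left.

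The fep1 mutation was examined in the ccr4 deletion, by comparing the double mutant with the ccr4 deletion alone. The fep1 gene (I 443100 to 446400) had a whole-cell extract level of −0.06 on the double mutant array, so its sequence was present there, and what kind of mutation the strain carried is not given in the sources used here. The ccr4 gene stood at −7.74. With the fep1 mutation, H3K9me2 was higher at many genes than in the ccr4 deletion alone. SPAC977.17 went from 0.63 to 4.97, SPAC186.08c (I 5544600 to 5545500) from 2.09 to 5.87, and SPAPB1A11.02 from −0.04 to 3.31. In total 179 of 4417 genes gained, at 53 loci, and the Ino80 subunit gene iec1 alone lost, by −0.70 (SD 0.59). Of the gains, 90 lay near a pericentromere, 39 near the ends of chromosomes I and II and 38 in the arms. Of the 109 genes lost in the ccr4 deletion, 69 were gained here, but both comparisons use the ccr4 array, so low values on that array alone would also give such an overlap.

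SPBC1289.14 rose by 2.98, glm1 by 2.81, the asparaginase gene SPAC186.03 by 2.53 and SPAC212.08c by 2.49. The gains at efm6 and ftm2 were 2.39 and 2.38, and gpx1 (II 2790600 to 2791200) rose by 2.32 to 3.74. Subtelomeric genes gained in 26 of 33 cases with a median of 1.96, which loess turned to −0.24, and Tf2 elements had a median of 0.48, which loess turned to −3.12, with 0 members passing the rule. Housekeeping genes had a median of −0.56, and centring on those genes, which removes such a median by construction, gave 0.07. These 3 medians lay outside the random range. The DSR list, median 0.01, gained ssm4 at 1.44, mug45 at 1.17 and mcp7 at 0.94. The stress list, median 0.13, gained gpx1 and tps1, the latter at 1.37, and the mating list, median 0.08, gained map1 at 0.97 and isp3 at 0.80. Single gains in other lists were gld1 at 1.39 among hexose genes (median −0.09) and sdh1 at 1.25 among iron-using genes (median 0.06). Another was per1 at 1.21 among amino acid transporters (median 0.18), a gene near a pericentromere, where many of the gains lay. Ribosomal protein genes had 2 gains among 41 and a median of 0.12. The iron-uptake, wtf, phosphate and machinery medians were −0.03, 0.03, 0.00 and 0.09. Of all calls 99.4% were gains, against 71.6% after loess, where SPAC186.03, SPAC212.08c and ftm2 were no longer called, and 87.5% with a common reference. Housekeeping centring moved the median of all genes by 0.63 and gave 334 gains, loess gave 68 gains and 27 losses, and a common reference 27 losses. The iec1 gene was not called with housekeeping centring, the median over probes, a common reference or a 2-fold difference.

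Bipyridyl treatment at 18 °C was compared with untreated wild type at 18 °C, to ask what iron depletion changed. The dose and time are not given in the sources used here. H3K9me2 fell at single genes in the arms, and 34 of the losses were at genes that had gained it in the cold. SPAC977.17 went from 4.50 to 0.80, a difference of −3.70 (SD 0.38), and SPBC1105.13c (II 3533100 to 3533700) differed by −3.61 (SD 0.69). SPBC428.10 went from 3.29 to 0.11 and gpx1 from 2.57 to −0.46. Of 4412 genes, 67 lost H3K9me2, at 54 loci, 45 of them in the arms, and 15 gained it, at 13 loci. Of the 62 losses also measured in the ccr4 deletion, 57 were lost there too, but both comparisons use the wild-type array, so high values on that array alone would also give such an overlap.

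SPBC1289.14 differed by −2.92, SPAPB1A11.02 by −2.86 and efm6 by −2.27. The difference of −2.80 at SPAC8C9.04 was a minimum loss, since 3 of its probes were saturated in wild type. The purine biosynthesis gene ade5 differed by −2.21 and gld1 by −2.08. All 10 named losses met the rule under every setting that was run. The gains were small, with vps29 at 0.96, the RNA polymerase subunit gene rpb8 at 0.85, SPBC17A3.08 at 0.71, cbs2 at 0.64, and cms1 and mdm34, each at 0.63. SPAC750.08c, mae2, tlh1 and mae1 rose by at most 0.94, 0.84, 0.78 and 0.63, since probes of each were saturated in wild type. Without saturated probes mae1 was measured and not called, and SPAC750.08c and tlh1, saturated in wild type at all 3 and at 18 of 19 probes, had too few left. SPAC750.08c and tlh1 also had too few left without repeated probes. None of these 10 reached 2-fold, and none was called once the arrays were rescaled to the same pericentromeric median.

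DSR genes had 6 losses among 17, led by ssm4 at −1.99, mug9 at −1.78 and mei4 at −1.60, and a median of −0.32 that centring on housekeeping genes turned to 0.01. Tf2 elements had 4 losses among 9 and a median of −0.82, including Tf2-9 at −1.27 and Tf2-1 at −1.11. The ribosomal protein median of −0.33, with 0 losses among 42, turned to 0.01 with housekeeping centring. These 3 medians lay outside the random range. Stress genes lost gpx1, at −3.04, and tps1, at −0.79, with a median of −0.12, and the mating genes isp3 and map1 fell by 1.49 and 0.79 with a list median of 0.01. The hexose list, median −0.02, had 1 loss, gld1. Iron-uptake genes had a median of −0.02 with 0 calls among 12, and among 19 iron-using genes, median 0.14, sdh1 rose by 0.60. Subtelomeric genes had 2 gains and 3 losses among 33 and a median of −0.03. The wtf, amino acid, machinery, housekeeping and phosphate medians were −0.10, 0.01, −0.08, −0.04 and 0.09. Of all calls 18.3% were gains, against 75.7% with housekeeping centring, which moved the median of all genes by 0.33, 2.06% after loess, 0 with rescaling and 29.3% with a common reference.

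The 39 genes that gained H3K9me2 at 18 °C were then followed over all 6 arrays. Their median level was 0.44 at 30 °C and 1.46 at 18 °C in wild type. It was 2.58 in the ago1 deletion, where 25 of the 39 gained further. It was 0.45 in the ccr4 deletion, where 34 of 36 measured genes lost, and 0.25 with bipyridyl, where 34 of 38 lost. In the double mutant it was 1.5, and 27 of 36 genes gained over the ccr4 deletion. The median differences were −1.25 (95% bootstrap interval −1.68 to −0.98) for the ccr4 deletion and −1.39 (−1.77 to −1.09) for bipyridyl. They were 0.73 (0.53 to 1.03) for the ago1 deletion, and 1.38 (0.83 to 1.57) for the double mutant against the ccr4 deletion. Across the scalings that were run the medians ranged from −1.72 to −1.18, from −1.53 to −1.05, from 0.57 to 0.90 and from 0.89 to 2.00 in that order. These genes were chosen on the wild-type 18 °C array, which also enters the comparisons with wild type; the double mutant and ccr4 deletion arrays played no part in the choice. The 179 genes that lost H3K9me2 in the cold had medians of 1.91 at 30 °C, 1.0 at 18 °C and 0.64 in the ago1 deletion. Of these genes, 48 lost further in the ago1 deletion and 20 gained. In the double mutant their median was 1.57, and 89 of 178 gained over the ccr4 deletion, with a median difference of 0.61 (0.55 to 0.66). A rise over the ccr4 deletion was thus not particular to the genes that gained in the cold.

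**Figure D3:**
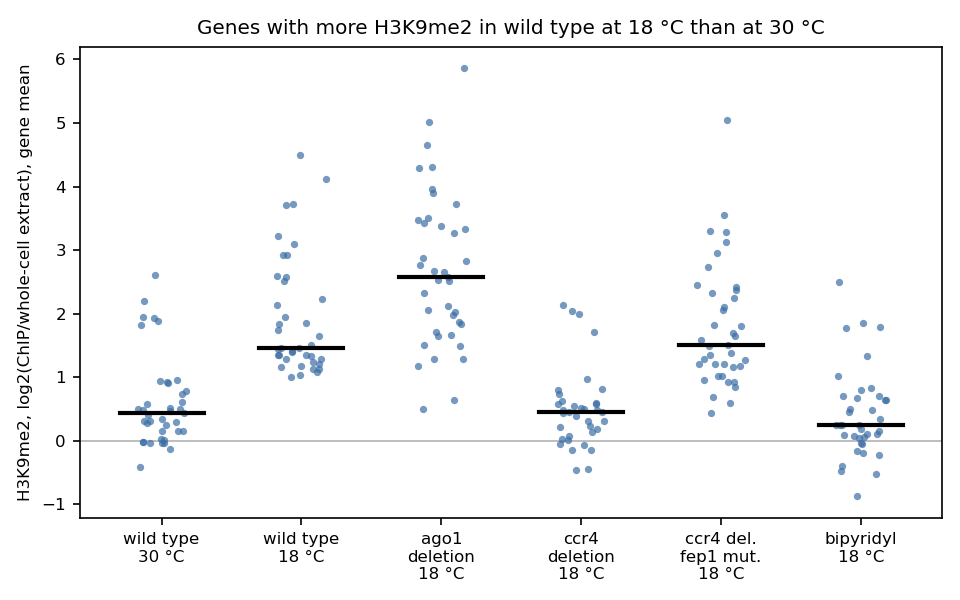
H3K9me2 (vertical axis, mean log2 ChIP over whole-cell extract per gene) of the 39 genes that gained the mark in wild type at 18 °C over 30 °C, on the 6 H3K9me2 arrays (horizontal axis); each point is a gene and each black bar the median. Medians were 0.44 at 30 °C, 1.46 at 18 °C, 2.58 in the ago1 deletion, 0.45 in the ccr4 deletion, 1.5 with the fep1 mutation added and 0.25 with bipyridyl.

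Fep1-GFP was mapped to ask which promoters it occupied. The fep1 gene itself had a whole-cell extract level of −0.01 on this array. Iron-uptake promoters were enriched. Of 13 in the fixed list, 12 reached 2-fold, with a median of 2.23 (95% bootstrap interval 1.96 to 2.79). The siderophore transporter promoters str2, str3 and str1 stood at 3.54, 2.79 and 2.65. The promoter of shu1 (I 87300 to 87900) reached 3.18, and the ferric reductase promoter frp2 (II 666900 to 667800) reached 2.87. The exception was pcl1 at 0.84. The highest promoter of all was that of cta3, a calcium-transporting ATPase (II 607200 to 607800), at 4.15 (SD 0.07). In total 353 of 5088 promoters at 189 loci reached 2-fold, and 61 reached 4-fold. Further named promoters were erg32 at 3.68, SPACUNK4.15 at 3.28, sds3 at 3.13, pta1 at 3.05, dps1 and tna1 at 3.00, the cyclin gene clg1 at 2.83 and the sorting nexin gene atg20 at 2.80. There was no array from an untagged strain, so signal that any ChIP would give at active promoters was not measured.

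Other lists were enriched as well. Hexose promoters had a median of 1.03, with 7 of 12 at 2-fold, among them ght2 at 2.1. Stress promoters had a median of 1.02, with 8 of 14 at 2-fold, including ssa1 at 1.97 and hsp16 at 1.75. Housekeeping promoters had a median of 0.99, with 6 of 13 at 2-fold, including adh1 at 2.07 and pgk1 at 1.70. Tf2 and wtf promoters had medians of 0.92 and 0.72, with 4 of 11 and 4 of 16 at 2-fold. Iron-using genes had a median of 0.44, which centring on housekeeping genes turned to −0.10, and 3 of 20 promoters at 2-fold, isu1 at 1.47, sir1 at 1.28 and aco1 at 1.25. The ribosomal median of 0.30, with 5 of 131 at 2-fold, turned to −0.23 with that centring. All these medians lay outside the random range. Inside it were the mating list at 0.06, with map2 at 2.55 and isp6 at 1.75, and the amino acid list at 0.42, with amt1 at 2.07 and isp5 at 1.96. The phosphate and DSR medians were 0.45 and 0.14, with pho8 at 1.55 and mcp7 at 1.24 the highest members. The machinery and subtelomeric medians were −0.13 and −0.03, with 0 promoters at 2-fold. Housekeeping centring moved the median of all promoters by −0.54 and left 130 promoters, normexp gave 531, and over a 500 bp window 6 of the 12 named promoters had too few probes to be measured and the other 6 were still called.

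Ssn6-Myc was compared between cells without and with fep1 to ask which of its promoters depended on Fep1. The fep1 gene had a whole-cell extract level of −3.81 on the deletion array and 0.09 on the other. Ssn6 was lost from iron-uptake promoters. All 13 in the list lost, with a median difference of −1.40 (95% bootstrap interval −1.91 to −0.87), from a median of 2.49 with fep1 to 0.94 without. The promoter of shu1 fell from 3.81 to 1.32, str3 from 3.63 to 1.27, frp2 from 2.49 to 0.28 and frp1 (II 163200 to 164100) from 3.12 to 1.20. Of 5088 promoters, 105 lost Ssn6, at 71 loci, and 62 gained it, at 48 loci. The promoter of cta3 kept a level of 3.67 after a loss from 4.70.

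Further losses were dps1 at −2.30, sds3 at −1.85, pta1 at −1.83 and SPBC887.17 at −1.80. The siderophore transporter promoter str1 differed by −1.62, the iron permease promoter fip1 by −1.54 and SPAC19G12.09 by −1.53. The largest gain was at gcd1 (III 241800 to 242400), by 1.44 (SD 0.23), followed by htr11 at 1.24 and the pentose phosphate gene gnd1 and dihydroxyacetone kinase gene dak2, each at 1.23. SPAC186.03 and plb5 each rose by 1.21, lnp1 by 1.16, SPAPB17E12.14c by 1.13, SPBC2A9.02 by 1.05 and the M-factor transporter gene mam1 by 0.99. Of the 61 promoters with at least 4-fold Fep1-GFP, 44 lost Ssn6 (72.1%), with a median difference of −1.01, and 0 gained it. Of the 292 with 2-fold to 4-fold Fep1-GFP, 36 lost it (12.3%). A loss needed Ssn6 at 2-fold with fep1, which most promoters with little Fep1-GFP did not have. Among the promoters that had it, 80 of 256 with 2-fold Fep1-GFP lost Ssn6 (31.2%), and 25 of 310 with less (8.06%).

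In the other lists few promoters changed. Hexose promoters, at 2.61 with fep1 and 2.63 without, had 1 gain, ght1 at 0.62, and 2 losses, cta3 at −1.03 and ght2 at −0.74, with a median difference of 0.10. The mating list, median −0.15, gained mam1 and lost map2 at −0.68 and isp6 at −0.60. The amino acid list, median −0.11, lost isp5 at −0.80 and amt1 at −0.60, and the stress list, median 0.06, lost hsp9 at −0.62. Housekeeping promoters, median 0.11, gained tdh1 at 0.63. The phosphate median of 0.42 and the ribosomal median of 0.07 lay outside the random range. So did the wtf median of −0.15 and the machinery median of 0.09, which turned to 0.01 and −0.01 with a common reference. The iron-using, DSR, Tf2 and subtelomeric medians were 0.02, −0.09, −0.15 and −0.02. Of all calls 37.1% were gains, against 24.0% with housekeeping centring, 26.8% with a common reference and 46.9% with normexp, which gave 159 gains and 180 losses, and SPAPB17E12.14c was not called with a common reference.

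**Figure D4:**
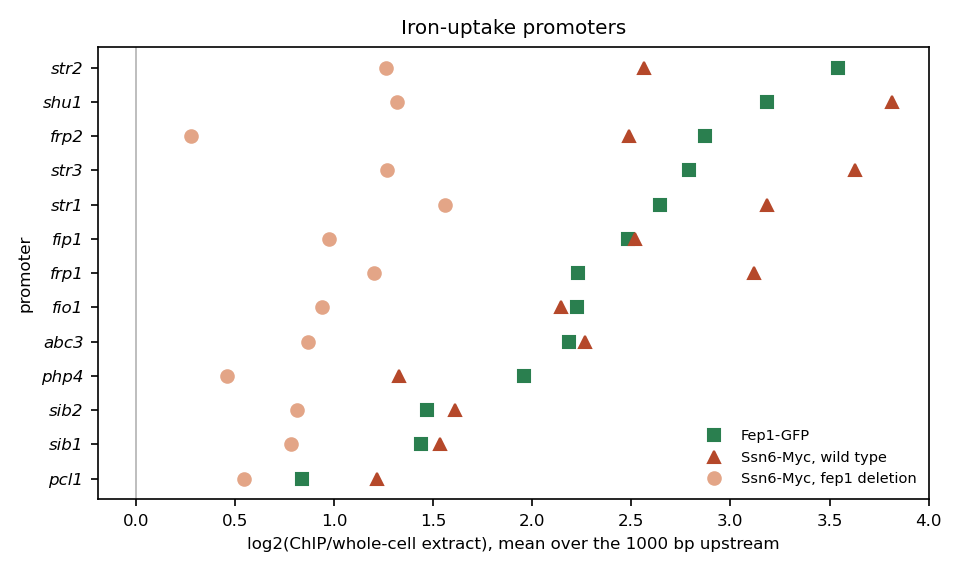
Mean log2 ChIP over whole-cell extract in the 1000 bp upstream (horizontal axis) of the 13 iron-uptake genes (vertical axis), for Fep1-GFP (squares), Ssn6-Myc with fep1 (triangles) and Ssn6-Myc without fep1 (circles), 1 array each. Each promoter had less Ssn6-Myc without fep1, with medians of 0.94 against 2.49, and 12 of 13 had Fep1-GFP at 2-fold or more.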

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

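Tests of loss of DNA and of dynamic range in the ccr4 deletion, of how many ago1 genes have any saturated or repeated probe and of the choice of genes on the wild-type array were written after the results had been seen, and the common whole-cell extract reference and the removal of saturated probes were settings added after the data had been seen.

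Signal appeared in data that no comparison uses. Probes of the telomere-linked clones had median H3K9me2 of 5.04 in wild type at 30 °C, 4.71 in wild type at 18 °C, 6.83 in the ago1 deletion, 7.0 in the ccr4 deletion, 7.38 in the double mutant and 5.71 with bipyridyl, against 0.74 to 1.13 on the Fep1 and Ssn6 arrays. Probes of the mating-type contig had 5.55, 5.93, 6.63, 6.56, 7.24 and 6.19 on the same 6 arrays, against −0.06 to 0.34 on the Fep1 and Ssn6 arrays. The whole-cell extract level of ura4, a gene no comparison targets, was −6.51 on the ccr4 deletion array and −7.18 on the double mutant array, against −1.22 in wild type at 18 °C.

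In the ccr4 deletion the telomere-linked clones kept H3K9me2, at 7.0 against at least 4.71 in wild type at 18 °C. The median over the subtelomeric probes was far lower than in wild type. Loss of subtelomeric DNA would lower the whole-cell extract signal of these probes. That signal was 1.07 higher than in wild type (0.96 to 1.20), but it was itself low in wild type, so a moderate loss could not show there. Against the Fep1-GFP array it was −0.34 (−0.45 to −0.17), a small drop beside the H3K9me2 difference of −4.27. A smaller dynamic range would lower pericentromeric values too. The difference of 0.99 (0.00 to 1.17) from wild type decides nothing, with 42.5% of those wild-type probes saturated. Against the bipyridyl array, with 0% saturated, values were 0.27 higher (0.07 to 0.73) over the probes measured on both arrays. Over all pericentromeric probes of each array, the ccr4 deletion median was instead slightly below the bipyridyl median. The sign thus depended on the probe set, but either gap was small beside the subtelomeric difference of −4.27. Low whole-cell extract signal on the wild-type array was removed by 1 common reference, which left a difference of −2.80 (−2.98 to −2.66) out of −4.27. These values argue against the 3 explanations as the whole cause, but the slide and scan of the single arrays stay open beside a role of Ccr4.

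In the ago1 deletion, 64 genes within 100 kb of the ends of chromosomes I and II gained H3K9me2. Leaving out saturated probes settles nothing, since the 68.75% still gained lost 0 probes, but the same 68.75%, 44 genes, had no saturated probe at all, which argues against saturation on the wild-type array for these and leaves it open for the other 20. With a common whole-cell extract reference 89.06% were still gained, with a median difference of 1.02 in place of 1.66, which argues against low whole-cell extract signal as the whole cause. Leaving out repeated probes settles nothing either, since only 1 of the 37 genes still measured (57.81% of all, each of them gained) lost a probe. Of the 64 genes 56.25%, 36 genes, had no repeated probe, which argues against cross-hybridisation of repeated probes for these and leaves it open for the others. For the pattern as a whole cross-hybridisation and a change in the mark cannot be told apart, and slide and scan stay open.

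The genes that gained H3K9me2 in the cold were lower in the ccr4 deletion and with bipyridyl. For the ccr4 deletion, choice of these genes on the wild-type array is argued against as the whole cause. The double mutant exceeded the ccr4 deletion by a median of 1.38 with a lower bound of 0.83, on arrays that had no part in the choice. For bipyridyl this comparison does not settle the choice, since it holds neither the bipyridyl nor the wild-type array. A smaller rise was also seen elsewhere. Genes that lost the mark in the cold rose by a median of 0.61 (0.55 to 0.66), and genes in the arms enriched in both wild-type arrays by 0.30 (0.21 to 0.51). A lower sensitivity of the ccr4 deletion array to enrichment in the arms may account for part of the loss there, since genes in the arms enriched in both wild-type arrays also differed, by a median of −0.94 (−1.08 to −0.12, 22 genes), past −0.63, which is 50% of the loss of the cold-gained genes, although the interval spans it. For bipyridyl the same genes differed by −0.67 (−0.92 to −0.10, 21 genes) against −0.69, by the same measure, so lower sensitivity and a loss at the cold-gained genes cannot be told apart. A biological explanation, that Ccr4 and iron are needed for the mark at these genes, thus stays open beside the technical ones.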

How the results depend on the processing

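Of 155 counts under other settings, 119 stayed within 1.5 times the main count and 36 moved. Of 170 list medians 127 stayed within their interval, 30 moved and 13 reversed. Of those that stayed, 34 came from random lists matched on the log2 ratio, a setting that cannot change a list's own median. Keeping non-uniform spots, the common Cy3 reference, leaving out saturated probes and list medians centred on housekeeping genes were added after the data had been seen. The series value table was not run as an alternative because its identifiers could not be paired, nor was rescaling for the ago1 deletion, which lost pericentromeric signal. No paired analysis was possible because each group had 1 array, and no array could be left out. Low Cy5 signal over background, with medians from 949.7 on H3K9me2 arrays, limits what can be seen at unmarked genes, and saturation limits the wild-type values at the strongest ones.

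By construction fewer genes passed a 2-fold difference: 24 gained and 75 lost at 18 °C, 94 gained in the ago1 deletion, 2 gained in the ccr4 deletion, 87 gained and 0 lost in the double mutant, 0 gained and 42 lost with bipyridyl, 9 gained and 41 lost for Ssn6, and 118 promoters at 3-fold for Fep1-GFP. More passed a 1.5-fold floor: 254 gained in the ago1 deletion, 41 gained in the ccr4 deletion, 19 lost in the double mutant and 43 gained with bipyridyl. Loess left 5 gained in the ccr4 deletion, 68 gained and 27 lost in the double mutant and 2 gained with bipyridyl. Housekeeping centring gave 1 gained in the ccr4 deletion, 334 gained and 0 lost in the double mutant, 143 gained with bipyridyl and 130 for Fep1-GFP. Normexp gave 6 lost in the double mutant, 531 for Fep1-GFP, and 159 gained and 180 lost for Ssn6. Rescaling to the same pericentromeric median gave 5 gained in the ccr4 deletion, and 0 gained and 114 lost with bipyridyl. The median over probes gave 2 lost in the double mutant. The common Cy3 reference gave 40 gained in the ccr4 deletion, 27 lost in the double mutant, 27 gained with bipyridyl and 183 lost for Ssn6. Apart from the thresholds, the cause was not tested.

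Loess reversed the ago1 medians of the wtf and hexose lists, both to −0.05, and the double mutant medians of Tf2 to −3.12 and of subtelomeric genes to −0.24. Housekeeping centring reversed the double mutant median of the housekeeping list to 0.07, which follows from centring on that same list. It also reversed the bipyridyl medians of DSR and ribosomal genes, both to 0.01, and the Fep1-GFP medians of iron-using genes to −0.10 and of ribosomal genes to −0.23. The common Cy3 reference reversed the medians of wtf genes to 0.27 and of phosphate genes to 0.08 at 18 °C, and for Ssn6 those of wtf genes to 0.01 and of machinery genes to −0.01. For the reversals other than that of the housekeeping list the cause was not tested. No count moved past 1.5 times without the dim-probe filter, without repeated probes, with non-uniform spots kept, without saturated probes or over a 500 bp window. Domain counts stayed within 1.5 times in 9 of 24 cases.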

Other observations

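None of the values in this part tests an explanation. The domain counts with the domains near the large regions included, and their alternative settings, were planned. The other values were looked at after the data had been seen.

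Broader classes of genes carried H3K9me2 at levels that the pairwise comparisons do not show. DSR meiotic genes had median levels of 0.95 in wild type at 30 °C, 0.66 in wild type at 18 °C, 0.90 in the ago1 deletion, 0.36 in the ccr4 deletion, and 0.51 both in the double mutant and with bipyridyl. Among them mcp7 stood at 4.53 in wild type at 30 °C and 2.35 at 18 °C. Of 17 DSR genes, 8 reached 2-fold in wild type at 18 °C and 4 with bipyridyl. Tf2 retrotransposons had medians of 1.23, 0.92 and 1.08 in wild type at 30 °C, wild type at 18 °C and the ago1 deletion, with 8, 4 and 7 of 9 elements at 2-fold. In the double mutant and with bipyridyl the Tf2 medians were 0.48 and 0.12, and 0 elements reached 2-fold there or in the ccr4 deletion.

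H3K9me2 domains in the arms, outside the large heterochromatic regions, numbered 92 in wild type at 30 °C and 105 at 18 °C, covering 164.1 and 192.6 kb with mean values of 1.73 and 1.81. The ago1 deletion had 183 domains over 392.1 kb, and the double mutant 141 over 217.8 kb with a mean of 1.93. The ccr4 deletion had 62 over 72.6 kb, mean 1.78, and the bipyridyl array 68 over 82.8 kb, mean 2.00. With the domains near the large regions included, the counts in the order 30 °C, 18 °C, ago1 deletion, ccr4 deletion, double mutant and bipyridyl were 146, 151, 232, 114, 208 and 111. They depended on the settings: 79, 77, 100, 53, 131 and 69 at 3-fold, 376, 260, 691, 314, 349 and 324 at 1.5-fold, and 103, 110, 235, 67, 131 and 66 without smoothing. The ends of chromosome III had median values of 0.28 and 0.67 in wild type at 30 °C and 18 °C, 2.07 in the ago1 deletion, 0.17 in the ccr4 deletion, 0.48 in the double mutant and 0.34 with bipyridyl.

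The ura4 gene had H3K9me2 of 6.93, 6.81 and 6.39 in wild type at 30 °C, wild type at 18 °C and bipyridyl, against 0.83 in the ago1 deletion. Its whole-cell extract level was 0.45 in the ago1 deletion, −1.44 and −1.22 on the wild-type arrays and −0.21 with bipyridyl. Where the gene stands in each strain is not given in the sources used here.

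Of the Ssn6-Myc array's promoters, 566 reached 2-fold with fep1, 552 without it, and 433 in both. Stress promoters had median Ssn6-Myc of 1.28 with fep1 and 1.46 without, housekeeping promoters 0.83 and 0.85, and subtelomeric promoters 0.68 and 0.69. Among promoters with Ssn6-Myc at 2-fold, the 310 with less than 2-fold Fep1-GFP had a median difference of −0.02 and the 256 others −0.21. Across all probes of the arrays, which are not independent replicates, Fep1-GFP and Ssn6-Myc values had a correlation of 0.638 with fep1 and 0.612 without.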
